A study of Danio rerio with 12 samples.

How the data were processed

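Zebrafish embryos of the wild-type AB line were grown at 23 °C to the 12-somite stage, per the labels. Pieces of tissue were dissected by hand from 6 positions along the paraxial mesoderm, the tissue that forms the somites, and placed in Trizol. Position 1 is the center of the tailbud and position 2 its flank. Positions 3, 4 and 5 are the posterior, center and anterior presomitic mesoderm (PSM). Position 6 is the last formed somites. Each position has 2 arrays, which the labels call biological replicates, so 12 arrays were analysed. How many embryos went into each sample is not given in the sources used here. Total RNA was amplified, and biotin-labelled cRNA from an in vitro transcription kit was hybridized to the Affymetrix Zebrafish array.

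The deposited values are an intensity per probe set, the MAS5 signal named in the submitters' processing notes with no version, on a linear scale. Checked on the values, the mean signal trimmed by 2% at each end was 150 on all 12 arrays, so 1 scaling factor per array had been applied. The table holds no detection calls, and a low signal is not called absent here. Signals ran from 0.1 to 16981. The table holds 15617 probe sets, of which 115 control probe sets were left out. Of the other 15502, 10795 carry 1 gene symbol, 135 carry several and 4572 carry none. Genes are named by symbol, and genome positions were not used here.

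The signals were analysed as log2 of the signal plus 12.2, the 25th percentile of all values. Folds are on this scale and understate changes of genes with low signals. Probe sets whose mean log2 value over the 12 arrays was below the 30th percentile were left out (4651), and 10851 were tested. No further normalization was applied. One linear model with 6 position means was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the intensity. All positions share 1 estimate of the spread per probe set, with 6 residual and 12.8 prior degrees of freedom. The tests were a moderated F test for any difference among the positions, a linear trend over the 6 positions (given as the fitted change from position 1 to position 6), position 6 against position 1, and the 5 steps between neighbours. All tests were two-sided. Benjamini-Hochberg adjustment was done within each comparison, and a call is an adjusted p under 0.05. "Rose", "fell", "higher" and "lower" are used of genes called in this way, unless a value is said not to be called. The number of arrays limits the precision: each position mean rests on 2 arrays, and errors printed beside signals are the SD with n = 2.

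The genes named were chosen by a rule. Each gene is represented by its probe set of highest mean, and its highest position mean had to exceed 97.8, the median signal of the tested probe sets. Clone and locus placeholders were left out. The rule takes the 12 largest rises and the 12 largest falls along the trend. It takes the 10 largest in each direction between the ends and the 4 largest in each direction at each step, where both arrays of one position lie above both of the other. It takes the 5 genes per middle position that peak there and exceed both ends by most. Members of gene lists are named as examples of their list. The 37 lists, the model, the rule and all alternatives except those named here as added were set before the data were examined. The lists cover developmental pathways, neighbouring tissues, cell growth and division, energy metabolism, Hox genes, matrix, adhesion and stress. They were tested along the trend and at each comparison with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on 6834 genes. A list of germ cell genes was added later for a single test.

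The alternatives were quantile normalization, median centring, no offset, an offset at the median (50.2), no filter, a filter at the 60th percentile, variances without the intensity trend, array weights, the replicate number as a block, a fit without position 2, a fit of only the 4 arrays of the 2 positions compared, 1 value per gene averaged over its probe sets, and each array left out in turn. Where an array is left out, the lone array of its position is assumed to vary like the others. A fit without the 3 arrays of highest median signal and a fit with the epidermal list's mean as a covariate were added after the results were seen. The whole procedure was tested on simulated data with 10851 probe sets, 50 of them changed by each size in each comparison. Along the trend it recovered 20% of simulated log2 changes of 1, 66% of changes of 2 and 96% of changes of 4, with 10 calls among unchanged probe sets. For single steps it recovered 36% to 58% of changes of 2 and 86% to 94% of changes of 4. A simulated list shifted by 0.5 had a camera p of 3.79e-11 in the limma fit, and an unshifted one 0.679. The simulated probe sets varied independently of each other. The simulation therefore does not test lists whose genes vary together, and the estimated correlation was 0.187 for ribosome biogenesis and 0.362 for epidermis. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.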

Results

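Transcript levels were measured on 12 arrays from 6 positions along the paraxial mesoderm of zebrafish embryos at the 12-somite stage, 2 biological replicates per position. The positions run from the center of the tailbud (position 1) over its flank (2) and the posterior, center and anterior PSM (3 to 5) to the last formed somites (6). The series asks how the transcriptome changes in space and time as tailbud cells become somites. The median signal per array ran from 27.3 to 68.4, although all arrays share a trimmed mean of 150. The 2 replicates correlated across probe sets with r between 0.831 at position 2 and 0.968 at position 6, where probe sets are not independent of each other.

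Along the axis from the tailbud to the somites, transcription factors of the mesodermal progenitors fell. *tbxta*, a T-box factor of the tailbud and notochord, had a signal of 1670 ± 396 (SD, n = 2) in the center of the tailbud, 199 ± 21.3 in the posterior PSM and 32.5 ± 1.84 in the somites. *tbx16*, *tbx16l* and *msgn1*, factors needed to make paraxial mesoderm, stayed high through the posterior PSM and fell anterior to it. *msgn1* measured 4575 ± 61.0 at position 1, 5374 ± 1088 at position 3, 1082 ± 192 at position 4 and 76.9 ± 69.2 at position 6, a fitted log2 change of -6.59 ± 0.32 (SE, adjusted p = 2.11e-11). *eve1*, a posterior homeobox gene, fell from 1630 ± 435 to 1.70 ± 0.566 (-7.19 ± 0.44, adjusted p = 5.76e-10).

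Other large falls included the ventral homeobox genes *vox* and *ved*, which act downstream of BMP, and *szl*, which encodes a secreted regulator of BMP signalling. *vox* fell from 1757 ± 539 to 44.0 ± 13.1 and *szl* from 647 ± 691 to 3.95 ± 1.2. The posterior Hox gene *hoxc11a* fell from 777 ± 119 to 7.35 ± 7.99, and 1 of its other probe sets changed by -0.95 without a call (adjusted p = 0.374). *cyp26a1*, whose product degrades retinoic acid, measured 3008 ± 202 at position 1, 77.6 ± 13.9 at position 5 and 225 ± 132 at position 6, a fitted trend of -4.73 and a direct difference between the ends of -3.79. *fam222aa* and *itm2cb* completed the 12 largest falls.

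The 12 largest rises included regulators of somite formation and muscle genes. *nr2f5*, an orphan nuclear receptor of the COUP-TF family, rose from 4.95 ± 2.62 to 3785 ± 24.7, with a higher mean at every next position and a fitted change of 7.53 ± 0.26 (184-fold, adjusted p = 3.33e-13). *aldh1a2*, which makes retinoic acid, rose from 20.1 ± 16.8 to 1795 ± 362 (6.68 ± 0.35, adjusted p = 8.02e-11), the opposite course to *cyp26a1*. *tcf15*, the somite factor paraxis, rose from 10.7 ± 0.212 to 1223 ± 18.5, and *dmrt2a* from 12.6 ± 1.34 to 614 ± 66.9. Muscle genes rose at different places. The myosin chaperone *hsp90aa1.1* reached 1544 ± 35.9 in the posterior PSM, while titin, *ttn.2*, measured 302 ± 56.5 in the anterior PSM and 1978 ± 176 in the somites. *fgfrl1a*, an FGF receptor-like gene, rose from 7.10 ± 6.22 to 887 ± 49.9. The other large rises were *cpn1*, *efemp2b*, *ston2*, *emp2* and *mafbb*.

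**Figure D1:**
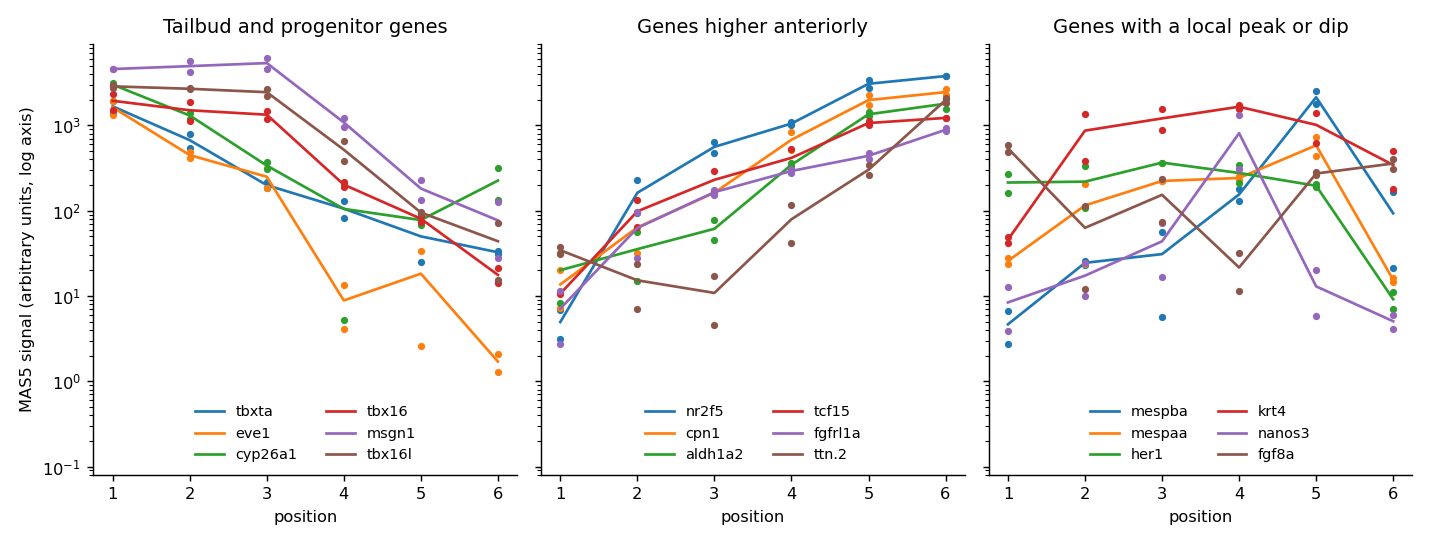
MAS5 signal (log axis) of 18 named genes at the 6 positions, with 1 point per array and a line through the position means. *tbxta*, *msgn1* and *cyp26a1* fell and *aldh1a2* and *nr2f5* rose toward the somites, while *mespba* peaked at position 5 with a mean of 2136.

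In total, 1434 of 10851 probe sets followed the linear trend, 770 higher toward the somites and 664 lower, and 977 of them changed at least 2-fold. The F test called 1210 probe sets (11.2%) for any difference among the positions, or 419 without the intensity trend in the variances, 774 without the 3 arrays of highest median signal and 777 with the epidermal covariate. In all 24 genes named for the trend, both arrays of one end lay above both of the other. Named genes had 10 other tested probe sets, and in the 19 comparisons made with them the sign was the same, 12 of them called and 7 not. Along the trend 409 were higher and 430 lower without the intensity trend. The median fitted change of all probe sets was -0.13 as deposited, 0.01 under quantile normalization and 0.24 under median centring. In the same order, 53.7%, 54.4% and 80.1% of the calls were higher toward the somites.

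Tested as a group, the tailbud progenitor list was the clearest to fall. Of its 17 measured genes, 12 fell and 0 rose with limma (13 and 0 adjusted over the list alone), with a median change of -3.36. Its camera adjusted p was 9.58e-12, and it was the only list of the 37 still called with an estimated correlation (adjusted p = 0.0091). Fry called 16 of the 37 lists along the trend, among them every list called by camera except blood, endothelium and intermediate mesoderm. Hox genes of groups 9 to 13, which pattern the posterior body, fell in 11 of 15 cases (13 adjusted over the list alone, median -1.43, camera adjusted p = 6.06e-10; adjusted p = 0.0548 with an estimated correlation). Hox genes of groups 1 to 8 were not called, with a median of -0.05 that turned to 0.19 under quantile normalization and 0.32 under median centring. In the Wnt list 8 of 19 genes fell and 3 rose (8 and 3 adjusted over the list alone), camera adjusted p = 0.00535 and adjusted p = 0.118 with an estimated correlation. The receptor gene *fzd10* fell by 3.47 on the log2 scale and *fzd7a* rose by 2.21, from 507 ± 353 to 1785 ± 239. In the BMP list 8 of 23 genes fell and 1 rose (9 and 1 adjusted over the list alone), camera adjusted p = 0.00455 and adjusted p = 0.118 with an estimated correlation. Of its genes 3 (*vox*, *szl*, *bambia*) are also in the progenitor list.

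The lists for cell division had medians below 0. Of 48 DNA replication genes, 14 fell and 2 rose (22 and 2 adjusted over the list alone), with a median of -0.61. The mean of that list, centred per gene, was 0.51 at position 1 and between -0.14 and -0.02 at positions 2 to 6, so its fall lay at the first step. *rrm1*, a subunit of ribonucleotide reductase, fell from 1754 ± 579 to 566 ± 183. Of 50 mitosis genes, 10 fell and 0 rose with limma (12 and 0 adjusted over the list alone), with a median of -0.41. The kinesin *kifc1* fell from 735 ± 21.6 to 214 ± 21.1 and the cyclin *ccna2* from 671 ± 26.4 to 199 ± 34.7. The camera adjusted p values were 4.29e-05 and 9.51e-05, and both lists had adjusted p = 0.259 with an estimated correlation. The size depended on the scaling: under median centring the medians were -0.24 for replication and -0.04 for mitosis, where all probe sets had 0.24.

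In the list for the anterior PSM and somite boundaries, 9 of 23 genes rose and 3 fell (11 and 4 adjusted over the list alone, median 0.85, camera adjusted p = 0.00695; adjusted p = 0.259 with an estimated correlation). Among them, *pcdh10b*, a protocadherin, rose from 39.5 ± 0.566 to 908 ± 94.3, and *tbx6*, which acts in boundary placement, peaked at position 4 with 861 ± 57.4. Of 10 myogenic transcription factors, 6 rose and 0 fell with limma (7 and 0 adjusted over the list alone, median 2.05, camera adjusted p = 0.000278; adjusted p = 0.0731 with an estimated correlation). Of 27 sarcomere genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone), and the actin gene *actc1a* rose from 769 ± 956 to 3946 ± 949. That list had a camera adjusted p of 0.00105, and adjusted p = 0.132 with an estimated correlation. The list for blood, endothelium and intermediate mesoderm had 7 of 20 genes higher (9 adjusted over the list alone, which also had 1 lower), camera adjusted p = 0.00535. It was not called with an estimated correlation (adjusted p = 0.504) or by fry (adjusted p = 0.156).

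Many genes for ribosome biogenesis rose by small amounts. Of 78 genes for ribosome biogenesis, 46 rose and 0 fell with limma (62 and 0 adjusted over the list alone). Their median change was 0.74 (camera adjusted p = 5.29e-19; adjusted p = 0.118 with an estimated correlation). *polr1a*, the large subunit of RNA polymerase I, rose from 65.2 ± 49.1 to 319 ± 24.8, and *mybbp1a* from 958 ± 274 to 2268 ± 413. Of 77 ribosomal protein genes 31 rose, of 78 translation factor and tRNA synthetase genes 18 rose and 2 fell, and of 91 genes for oxidative phosphorylation 14 rose. Adjusted over the list alone, 53, 28 and 16 rose. Medians were 0.44, 0.33 and 0.25, against -0.13 for all probe sets, and camera adjusted p was 2.89e-14, 4.94e-06 and 1.62e-05. With an estimated correlation none of these 3 was called (adjusted p = 0.259, adjusted p = 0.29 and adjusted p = 0.379). Each of the 14 lists called by camera kept the sign of its median under quantile normalization and median centring, where the ribosomal protein median was 0.09 and 0.81.

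**Figure D2:**
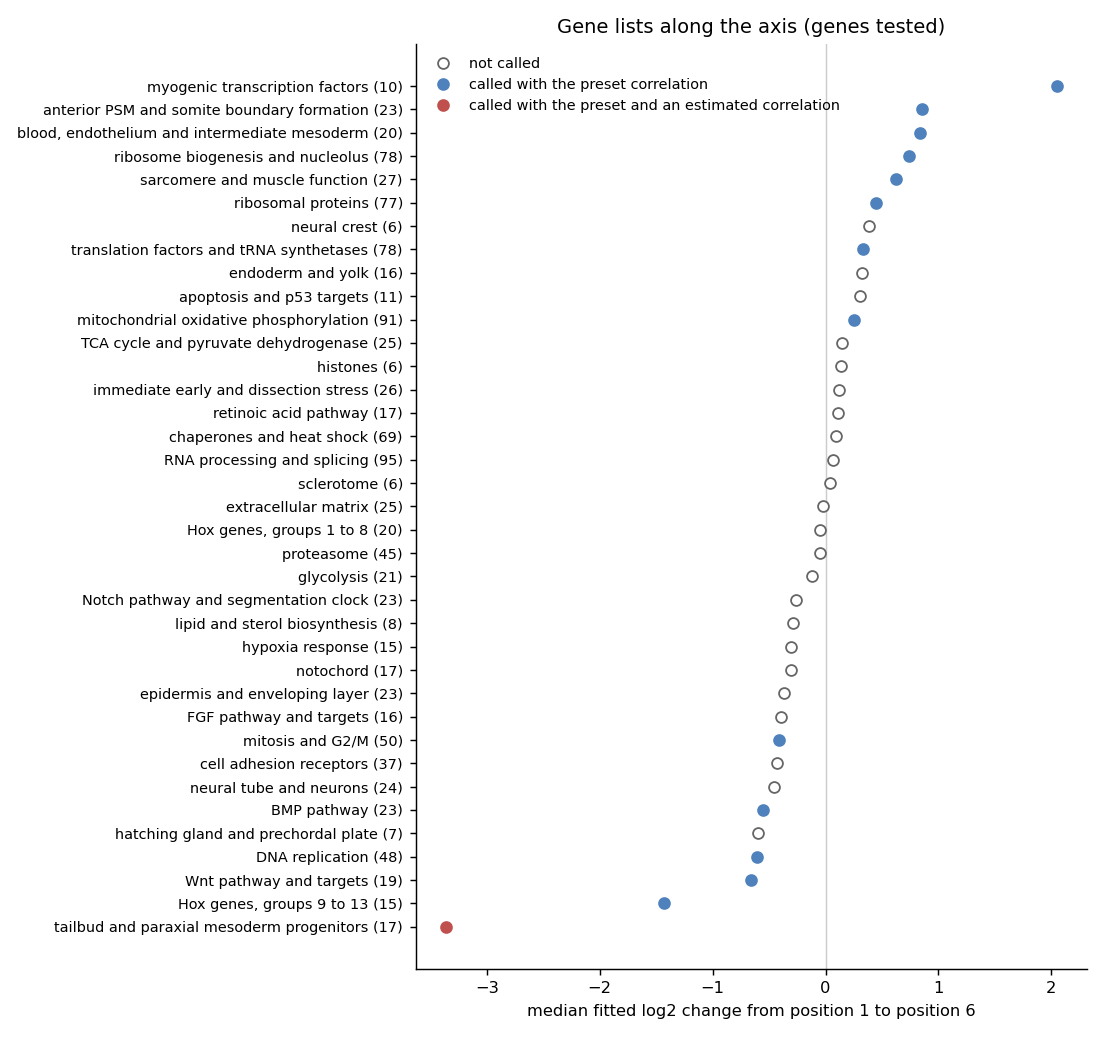
Median fitted log2 change from position 1 to position 6 of the genes of each list, with the lists called by camera marked. The tailbud progenitor list lies lowest at -3.36 and the myogenic transcription factors highest at 2.05.

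Several pathways held genes that went opposite ways, and their lists were not called. In the Notch and clock list 4 of 23 genes rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.691). The genes *her1*, *her7* and *hes6* fell, *her7* from 394 ± 253 to 16.2 ± 9.90. In contrast, *hey1* rose from 72.5 ± 18.6 to 1152 ± 41.9 and *notch2* from 89.0 ± 12.3 to 1053 ± 24.2. The ligand gene *dld* was not called and measured 1109 ± 62.0 and 1300 ± 0.990 at the ends. In the FGF list 3 of 16 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.617): the receptor *fgfr4* rose from 21.3 ± 21 to 463 ± 51.1, and the ligand *fgf10a* fell from 372 ± 18.2 to 39.5 ± 17.0. In the retinoic acid list 4 of 17 rose and 5 fell (5 and 5 adjusted over the list alone, adjusted p = 0.335, by fry adjusted p = 0.00181). There *nr2f1a* and *nr2f2* rose beside *aldh1a2* and *nr2f5*, and the receptors *rarga* and *raraa* fell, *rarga* from 869 ± 33.5 to 74.7 ± 50.4. Matrix genes went both ways (4 of 25 rose and 3 fell, 6 and 4 adjusted over the list alone, adjusted p = 0.482), with *col11a1a* falling from 613 ± 37.1 to 82.6 ± 42.6. Of 37 adhesion receptors 3 rose and 7 fell (4 and 9 adjusted over the list alone, adjusted p = 0.129, by fry adjusted p = 0.00735). Of 69 chaperones 12 rose and 5 fell (13 and 6 adjusted over the list alone, adjusted p = 0.276), and *pdia4* fell from 537 ± 84.6 to 49.2 ± 43.4. Of 26 immediate early genes 6 rose and 2 fell (6 and 5 adjusted over the list alone, adjusted p = 0.482). *ier2a* fell from 1659 ± 118 to 472 ± 129.

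The other lists had few called genes, and camera called none of them. In the notochord list 1 of 17 rose and 3 fell (adjusted p = 0.23, by fry adjusted p = 0.0355), and in the neural tube list 1 of 24 rose and 4 fell (adjusted p = 0.29; called with adjusted p = 0.0424 under median centring and 0.0133 without replicate 1 of position 1). In neural crest 2 of 6 rose and 1 fell (adjusted p = 0.306), and in epidermis 1 of 23 rose and 1 fell (adjusted p = 0.771). In RNA processing 4 of 95 rose and 2 fell (adjusted p = 0.335), in the proteasome 1 of 45 rose and 1 fell (adjusted p = 0.953), and in the TCA cycle 1 of 25 rose and 2 fell (adjusted p = 0.335). Glycolysis had 2 of 21 higher (adjusted p = 0.761), although its median of -0.12 and its camera direction differed in sign, as they did for sclerotome (median 0.04) and matrix genes (median -0.03). Histones had 1 of 6 higher (adjusted p = 0.482), apoptosis and p53 targets 1 of 11 higher (adjusted p = 0.276), hypoxia 1 of 15 lower (adjusted p = 0.482) and Hox groups 1 to 8 had 2 of 20 lower (adjusted p = 0.482). Adjusted over the list alone, these 12 lists gave 0 to 3 rises and 0 to 4 falls with limma. The lists for sclerotome, endoderm and yolk, hatching gland, and lipid and sterol synthesis had 0 called genes with limma, also adjusted over the list alone. Their camera adjusted p values were 0.994, 0.471, 0.335 and 0.45, and by fry 0.823, 0.433, 0.156 and 0.163.

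The ends of the axis, the somites and the center of the tailbud, were also compared directly. *nr2f5* was 223-fold higher in the somites (7.80 ± 0.30, adjusted p = 3.82e-12), and *eve1* was 116-fold lower (-6.86 ± 0.52, adjusted p = 2.34e-08). These sizes depend on the setting: the log2 change ran from 6.12 to 9.69 for *nr2f5* and from -9.92 to -4.99 for *eve1*. *hoxd11a*, another posterior Hox gene, measured 805 ± 49.9 at position 1, 812 ± 82.3 at position 3 and 14 ± 10.04 at position 6. In total 1082 probe sets were called, 587 higher and 495 lower in the somites. Leaving out 1 somite array left 367 (without replicate 1) or 319 (without replicate 2) higher and 315 or 288 lower, and leaving out 1 tailbud array left 307 (without replicate 1) or 317 (without replicate 2) lower. Under median centring 177 were lower, and without the intensity trend in the variances 274 were higher and 253 lower.

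The steps between neighbours show where along the axis the levels changed. From the center to the flank of the tailbud (position 1 to 2), several genes of the epidermis rose, and the medians of several other lists were above 0. The arrays of the flank lay apart: the mean of the epidermal list, centred per gene, was 0.06 on the left (replicate 1) and 1.09 on the right (replicate 2), against -1.21 and -0.82 at position 1. That of the blood and endothelium list was -0.59 and 0.82, against -1.18 and -1.05, so the right array carried more of both changes. The keratin *krt4* rose from 45.7 ± 5.37 to 867 ± 683 (3.67 ± 0.49, adjusted p = 0.000893), the tight junction gene *cldni* from 371 ± 226 to 2217 ± 732 and *epcam* from 277 ± 168 to 1290 ± 672. *fli1*, a factor of the endothelium, rose from 2.95 ± 0.495 to 185 ± 126 (adjusted p = 0.00127), although its other probe set was not called (0.92, adjusted p = 0.583). *csrp1a* and *myo9b* were the other large rises. Of 23 epidermal genes 9 rose and 0 fell with limma (15 and 0 adjusted over the list alone), with a median of 1.96 and camera adjusted p = 5.28e-08. The list was not called with an estimated correlation (adjusted p = 0.326) or by fry (adjusted p = 0.068). Camera also called the blood and endothelium list (median 1.53, adjusted p = 0.00907), sclerotome (1.19, adjusted p = 0.00652), endoderm and yolk (1.04, adjusted p = 0.00634), matrix (0.83, adjusted p = 0.00652) and anterior PSM (0.79, adjusted p = 0.0028), none of them with an estimated correlation (adjusted p between 0.153 and 0.629). Called higher by limma were 2, 0, 3, 1 and 4 of their genes (6, 2, 5, 5 and 9 adjusted over the list alone). In the same order, fry gave adjusted p = 0.227, 0.0273, 0.0286, 0.0273 and 0.0286.

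At the same step single genes fell, among them signalling genes whose lists were not called. The ligand *fgf8a* fell from 538 ± 69.1 to 62.9 ± 71.8 (adjusted p = 0.00411), *foxd3* from 670 ± 33.3 to 71.8 ± 31.5 and the Wnt target *axin2* from 917 ± 734 to 163 ± 13.4. *sox19a* and *psmc3ip* were also lower at position 2. The arrays of position 1 lay apart here, with *sox19a* at 70.4 and 847 in replicates 1 and 2. Their centred list means were -0.48 and 0.91 for neural tube and -0.31 and 0.82 for notochord. The FGF list had 1 gene higher and 2 lower of 16 (1 and 4 adjusted over the list alone) and the Wnt list 1 lower of 19 (1 higher and 2 lower adjusted over the list alone), both with camera adjusted p = 0.994. The progenitor list had 1 of 17 lower (4 adjusted over the list alone), with camera adjusted p = 0.0129 and adjusted p = 0.153 with an estimated correlation. In the DNA replication list 4 of 48 genes fell (22 adjusted over the list alone, median -0.62, camera adjusted p = 6.3e-12; adjusted p = 0.153 with an estimated correlation). They were *mcm2*, *slbp*, *dnmt1* and *pold1*, with *mcm2* falling from 2381 ± 486 to 972 ± 323. Camera also called mitosis (median -0.29, adjusted p = 4.36e-05), the proteasome (-0.25, adjusted p = 0.00348) and RNA processing (-0.16, adjusted p = 0.0039) lower, none of them with an estimated correlation (adjusted p between 0.25 and 0.629). Called lower by limma were 1, 2 and 0 of their genes (5, 2 and 0 adjusted over the list alone). Fry gave adjusted p = 0.0273 for DNA replication, 0.0286 for mitosis, 0.306 for the proteasome and 0.108 for RNA processing. Counts of calls per step rest on 1 spread for all positions. The replicate pairs, however, differed by a median of 0.52 log2 at position 2 and 0.32 at position 6. The counts of steps that touch these positions are therefore not strictly comparable. At this step 166 probe sets were called, 120 higher and 46 lower, more than at the step from position 5 to 6 (131). That order turned under median centring (273 against 295), with array weights (76 against 398), with only the 4 arrays compared (56 against 240), with the epidermal covariate (0 against 93) and without replicate 2 of position 1 (84 against 189). Without replicate 1 of position 1 there were 251 calls and without its replicate 2 there were 84. Variances without the intensity trend gave 14 calls, and with the epidermal list's mean as a covariate limma called 0 (936 at an unadjusted p under 0.05). *foxd3* lost its call without any 1 of the 8 arrays of positions 1 to 4, *sox19a* without replicate 2 of position 1 or either array of position 2, and *psmc3ip* without replicate 2 of position 1.

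From the flank of the tailbud to the posterior PSM (position 2 to 3), 14 probe sets were called. *wif1*, a secreted Wnt inhibitor, rose from 37.5 ± 12.4 to 409 ± 54.6 (3.10 ± 0.35, adjusted p = 0.000398), and *hsp90aa1.1* rose from 135 ± 173 to 1544 ± 35.9 (adjusted p = 0.0223). *sox19a* and *tuba8l3* were also higher. *szl* fell from 895 ± 30.6 to 27.5 ± 31.1 (-4.78 ± 0.73, adjusted p = 0.0101). Ribosome biogenesis genes had a median of 0.39 with 0 of 78 called by limma (3 adjusted over the list alone, camera adjusted p = 5.59e-09; adjusted p = 0.669 with an estimated correlation). Camera also called BMP lower (median -0.66, adjusted p = 0.00054) and neural tube (0.89, adjusted p = 0.0138) and translation (0.22, adjusted p = 0.023) higher, none with an estimated correlation (adjusted p between 0.145 and 0.833). The count rested on single arrays: 91 and 22 probe sets were called without replicate 2 and 1 of position 2, 5 and 2 without replicate 1 and 2 of position 3, and 28 without either array of position 1. Only the 4 arrays compared gave 46, the filter at the 60th percentile 7 and array weights 5. With variances that ignore the intensity, or without the 3 arrays of highest median signal, limma called 0 (1037 and 967 at an unadjusted p under 0.05), and *wif1* lost its call. *hsp90aa1.1* lost its call without replicate 2 of position 2 or any array of positions 3 and 4, *tuba8l3* without replicate 1 of position 2 or any array of positions 3, 4 and 6, *sox19a* without any array of positions 2 to 6, and *szl* without replicate 2 of position 3.

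From the posterior to the center PSM (position 3 to 4), several progenitor factors fell. *tbx16* fell from 1334 ± 202 to 202 ± 18.7 (-2.65 ± 0.29, adjusted p = 0.000122), *eve1* from 250 ± 93.5 to 8.85 ± 6.72 (adjusted p = 0.00178) and the Wnt target *sp5l* from 1255 ± 85.2 to 241 ± 10.9 (adjusted p = 0.000121). *ved* was also lower. *aldh1a2* began its rise here, from 61.3 ± 22.1 to 345 ± 20.8 (2.31 ± 0.42, adjusted p = 0.017). *jun*, *flncb* and the germ cell gene *nanos3* were also higher at position 4. *jun* came back from a low mean of 10.15 ± 4.03 at position 3, after 186 ± 210 at position 2, and measured 111 ± 5.73 at position 5. *nanos3* had a peak at position 4 and fell at the next step. The other probe set of *jun* was not called (1.96, adjusted p = 0.62). Of 17 progenitor genes 4 fell (7 adjusted over the list alone, median -0.87, camera adjusted p = 3.63e-06; adjusted p = 0.0507 with an estimated correlation). Camera also called Wnt (median -0.31), mitosis (-0.24) and Hox groups 9 to 13 (-0.24) lower, each with adjusted p = 0.00361, and blood higher (1.47, adjusted p = 2.31e-07), none with an estimated correlation (adjusted p between 0.188 and 0.646). In all 24 probe sets were called, 12 in each direction. The count was 12 or 9 without replicate 1 or 2 of position 3, and 12 without replicate 2 of position 4. It was 99 with only the 4 arrays compared, 12 with no offset, 2 without the intensity trend in the variances and 1 without the 3 arrays of highest median signal, and in both fits *tbx16* and *sp5l* lost their calls (adjusted p = 0.0878 and 0.115 in the latter). *aldh1a2* lost its call without any array of positions 3 and 4, and *ved* without any of positions 2, 3 and 4. *jun* and *flncb* lost theirs without either array of position 3 or 1 array of position 4 (replicate 2 for *jun*, replicate 1 for *flncb*), *nanos3* without either array of position 3, replicate 1 of position 4 or any array of positions 5 and 6, and *eve1* without replicate 2 of position 3.

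From the center to the anterior PSM (position 4 to 5), the segmentation factor *mespba* came on. It rose from 155 ± 37.6 to 2136 ± 521 (3.68 ± 0.67, adjusted p = 0.0214). The kinase gene *plk3* rose from 258 ± 5.45 to 1624 ± 96.4 (2.60 ± 0.24, adjusted p = 2.2e-05), *fgf8a* from 21.6 ± 14.4 to 273 ± 14.4 and *plpp1a* from 133 ± 43.0 to 829 ± 19.8. *msgn1* fell to 182 ± 66.3 (-2.53 ± 0.38, adjusted p = 0.00374; its other probe set missed the threshold with -2.42, adjusted p = 0.0547), and *fam222aa* also fell. The germ cell genes *nanos3* and *dnd1* fell, *nanos3* from 810 ± 716 to 12.95 ± 10.1. Of 16 FGF genes 1 rose and 1 fell (1 and 5 adjusted over the list alone). Camera called that list lower (median -0.43, adjusted p = 0.0177), though not with an estimated correlation (adjusted p = 0.203), and fry called it too (adjusted p = 0.00248). Fry also called progenitors (adjusted p = 0.00936) and Hox groups 9 to 13 (adjusted p = 0.0341). Camera also called epidermis (adjusted p = 3.34e-05), Hox groups 9 to 13 (median -0.62, adjusted p = 4.24e-05), progenitors (adjusted p = 0.000645), BMP, blood and endoderm lower, and ribosome biogenesis (0.23, adjusted p = 1.06e-05), anterior PSM (0.32, adjusted p = 0.00107), myogenic factors, ribosomal proteins, translation and RNA processing higher. None of these 12 was called with an estimated correlation (adjusted p between 0.191 and 0.636), and limma called 0 of 23 epidermal and 0 of 78 ribosome biogenesis genes (4 and 0 lower adjusted over the list alone; both by fry adjusted p = 0.339). In all 23 probe sets were called. The count was 10 without either array of position 4, 5 and 7 without replicate 1 and 2 of position 5, 36 without either array of position 1, and 50 and 45 without replicate 1 and 2 of position 2. Only the 4 arrays compared gave 92, the offset at the median 42, array weights 35, the filter at the 60th percentile 13 and the epidermal covariate 9. With variances that ignore the intensity limma called 0, with 879 at an unadjusted p under 0.05, and without the 3 arrays of highest median signal it called 6. *mespba*, *fgf8a* and *plpp1a* lost their calls without any 1 array of positions 4 and 5 (*plpp1a* also of position 6), *nanos3* and *dnd1* without replicate 1 of position 4 or either array of position 5, *fam222aa* without either array of position 4 or replicate 1 of position 5, and *msgn1* without replicate 1 of position 4 or replicate 2 of position 5.

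From the anterior PSM to the last formed somites (position 5 to 6), some segmentation genes fell. *mespba* fell to 93.1 ± 102 (-4.78 ± 0.67, adjusted p = 0.000915), *mespaa* from 583 ± 200 to 15.5 ± 1.2 (adjusted p = 0.000533), the clock gene *her1* from 196 ± 11.6 to 9.15 ± 2.90 (adjusted p = 0.000533) and *foxc1a* from 1271 ± 74.5 to 301 ± 50.1. *znf346* also fell. Of the 23 anterior PSM genes 3 fell and 0 rose with limma (6 and 1 adjusted over the list alone), and of the 23 Notch and clock genes 2 fell and 0 rose (4 and 2 adjusted over the list alone), and neither list was called by camera (adjusted p = 0.0605 and 0.752) or by fry (0.139 and 0.386). Of 23 epidermal genes 2 fell (6 adjusted over the list alone, median -0.69, camera adjusted p = 0.0192, and adjusted p = 0.872 with an estimated correlation). Between single arrays the median change of that list was -1.65 and -1.23 to replicate 1 of position 6, but only -0.36 and -0.09 to its replicate 2. Progenitors and Hox groups 9 to 13 were called lower and sarcomere genes higher by camera, each with adjusted p = 0.0489 and none with an estimated correlation (adjusted p between 0.553 and 0.771). By fry these 3 lists had adjusted p = 0.0119, 0.0356 and 0.54. In the FGF list *spry4* rose from 41.9 ± 20.1 to 322 ± 26.8 (adjusted p = 0.00196) and *dusp6* from 542 ± 130 to 2402 ± 5.51 (2.14, adjusted p = 1.7e-05). These were the 2 of 16 genes higher (2 adjusted over the list alone). The list median was 0.35 (camera adjusted p = 9.45e-05, by fry adjusted p = 0.000202, and adjusted p = 0.111 by camera with an estimated correlation). This rise followed a dip: the centred list mean was 0.05 at position 4, -0.38 at position 5 and 0.23 at position 6. *spry4* had 199.3 and 258.5 in the arrays of position 4. The matrix gene *tgfbi* rose from 186 ± 19.2 to 1333 ± 158, *ttn.2* rose 6.38-fold with an uncalled second probe set (1.57, adjusted p = 0.312), and *usp42* rose with another such (0.41, adjusted p = 0.859). In all 131 probe sets were called, 76 higher and 55 lower. The count was 39 and 33 without replicate 1 and 2 of position 5, and 56 without replicate 2 of position 6. It was 295 under median centring, 240 with only the 4 arrays compared, 66 under quantile normalization, 398 with array weights and 67 without the 3 arrays of highest median signal. Without the intensity trend limma called 0, with 1214 at an unadjusted p under 0.05, and of all genes named at the 5 steps only *myo9b* kept its call. *usp42*, *ttn.2* and *znf346* lost their calls without any 1 array of positions 5 and 6 (*znf346* also of positions 3 and 4), and *spry4* without replicate 1 of position 5.

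**Figure D3:**
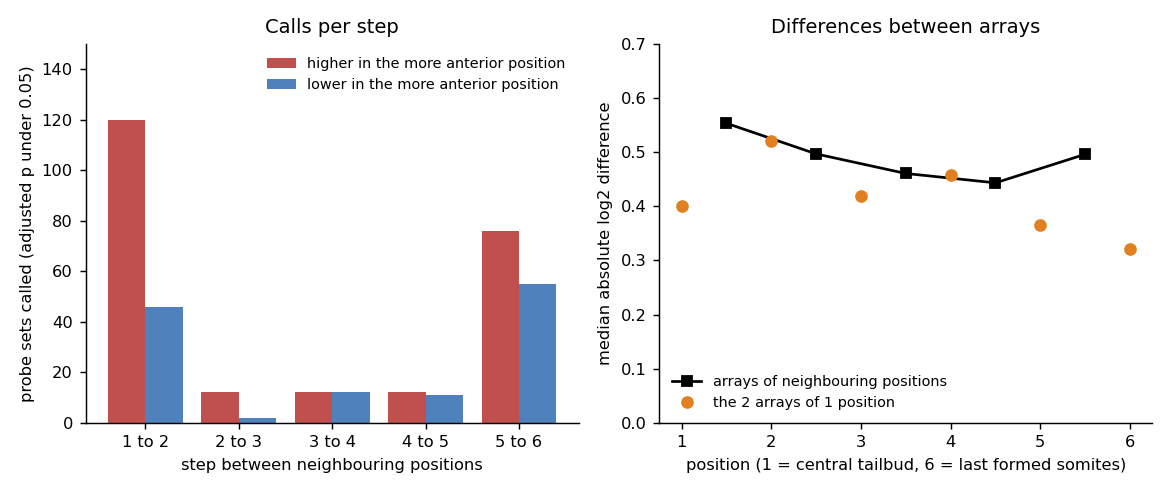
Left, probe sets called higher and lower at each step between neighbouring positions. Right, the median absolute log2 difference between single arrays for each step and for the replicate pair of each position, with the first step at 0.55 and the position 2 pair at 0.52.

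Some genes had their highest mean in the middle of the axis. Among the 1210 probe sets of the F test, the highest mean was at position 1 in 275, position 2 in 203, position 3 in 74, position 4 in 113, position 5 in 104 and position 6 in 441. *mespba* and *mespaa* peaked at position 5, by 4.78 and 3.93 on the log2 scale above the higher end, with *znf346*, *sypb* and *tsc22d2*. At position 4, *nanos3* exceeded the ends by 5.01, and *krt8*, a keratin, measured 1070 ± 77.0 there against 110 ± 12.5 at position 1 and 159 ± 53.6 at position 6. *acy3.2*, *hand2* and *apoc2* had their highest means at the same place. The collagen gene *col1a1a* peaked at position 2 with 523 ± 177, beside *csrp1a*, *capn8*, *astn1* and *fam49ba*. The laminin gene *lama5* had its highest mean at position 3 with 262 ± 50.3, beside the neuronal gene *elavl3*, *cavin2a*, *ankhb* and *smox*. Both arrays of the position exceeded all others for 7 of these 20 genes (*mespba*, *mespaa*, *sypb*, *tsc22d2*, *nanos3*, *krt8*, *col1a1a*), and for the other 13 the single arrays leave the place of the peak open. *acy3.2* had 213 and 646 at position 4 against 314 in 1 array of position 3, *hand2* had 83.9 and 813 against 196 in 1 array of position 2, and *apoc2* had 116 and 141 against 147 there. Without replicate 1 of position 6 the counts at positions 2, 3, 4 and 6 were 106, 43, 67 and 283, and without its replicate 2 those at positions 2, 3 and 6 were 128, 48 and 278. Position 4 had 177 without replicate 2 of position 2 and 71 without replicate 2 of position 4. *apoc2* lost its call in the F test without any 1 array of positions 1, 3, 4, 5 and 6, *hand2* without either array of positions 5 and 6 or replicate 2 of positions 2, 3 and 4, and *astn1* without any of positions 2, 3 and 5 or replicate 2 of position 4. *smox* lost it without either array of position 3 or replicate 1 of position 6, *elavl3* without replicate 2 of position 5, and *znf346* without replicate 1 of position 6.

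**Figure D4:**
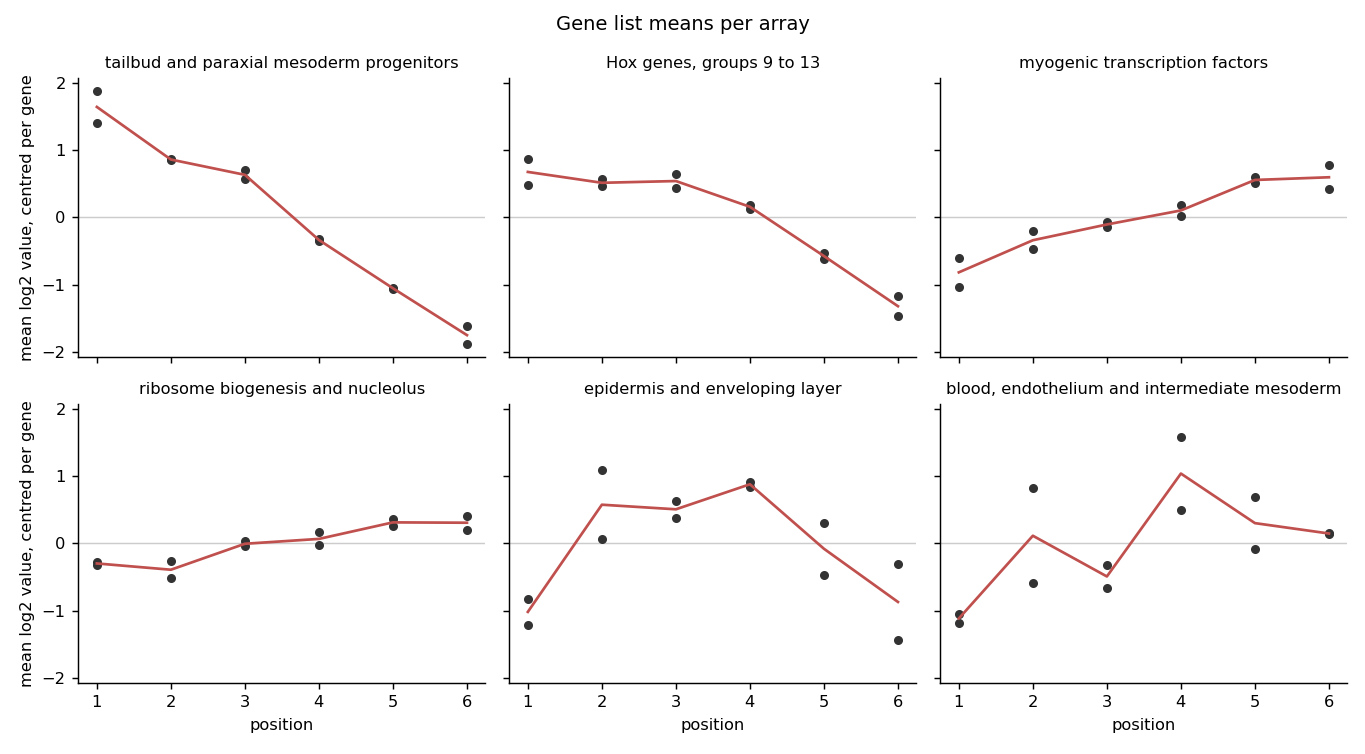
Mean log2 value of the genes of 6 lists, centred per gene, at the 6 positions, with 1 point per array and a line through the means. The mean of the progenitor list went down and that of the ribosome biogenesis list went up toward the somites. The epidermal list had its lowest means at positions 1 and 6. Its 2 arrays of position 6 lay at -1.43 and -0.305, the second above replicate 2 of position 5 at -0.465.

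The replicates of position 2 came from the left (replicate 1) and the right (replicate 2) flank, so side and replicate cannot be separated there. They differed by a median of 0.52 log2, and 6.88% of probe sets differed more than 4-fold. The replicate pairs of the other positions differed by 0.32 to 0.46, with 0.129% to 5.00% of probe sets above 4-fold. No test was run with 1 array per side.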

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

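The fit without the 3 arrays of highest median signal (replicate 1 of position 2 and replicate 2 of positions 3 and 4, at 68.4, 63.8 and 67.7) and the fit with the epidermal list's mean as a covariate were chosen after the results were seen. The other alternatives were planned.

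The trend and end genes held best. The 24 genes named for the trend and the 20 named for the ends kept their direction and their call in all alternatives run for them. Over all named genes and alternatives, 2044 values kept direction and call, 250 lost the call and 0 reversed, where a gene named in several comparisons counts in each. Over the lists 689 kept direction and call, 14 lost the call and 5 gained it, and 32 medians of 15 lists changed sign, none of them called there or in the reported fit. Median centring, which moved the median of all probe sets from -0.13 to 0.24, turned Notch and clock (0.10), notochord (0.0571), proteasome (0.31), glycolysis (0.25), Hox groups 1 to 8 (0.32), matrix (0.34), hypoxia (0.0563) and lipid synthesis (0.0733). Quantile normalization turned RNA processing (-0.0372), glycolysis (0.0911), Hox groups 1 to 8 (0.19) and matrix (0.24), and no filter turned retinoic acid (-0.10) and neural crest (-0.0270). With 1 array left out the medians ran from -0.29 to 0.34 (sclerotome), -0.56 to 0.14 (epidermis), -0.69 to 0.0117 (hatching gland), -0.13 to 0.25 (matrix), -0.19 to 0.40 (immediate early), -0.13 to 0.33 (retinoic acid), -0.20 to 0.14 (proteasome) and -0.18 to 0.96 (neural crest). Apart from median centring the cause was not tested. Of the 1434 trend calls, 1164 were shared with the 1273 under quantile normalization and 1028 with the 1317 under median centring.

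Median centring left 262 probe sets lower along the trend and 177 lower at the ends, with 273 calls at step 1 to 2 and 295 at step 5 to 6. It shifts every probe set by the median of its array, and the medians ran from 27.3 in the somites to 68.4 at position 2. Quantile normalization gave 66 at step 5 to 6.

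Variances without the intensity trend gave 419 calls in the F test, 409 higher and 430 lower along the trend, 274 higher and 253 lower at the ends, and 14, 0, 2, 0 and 0 at the steps in order (limma, with 1507, 1037, 873, 879 and 1214 at an unadjusted p under 0.05). The prior degrees of freedom were 2.92 there and 12.8 in the reported fit, so less of the spread was shared between probe sets. Array weights gave 76, 5, 35 and 398 at steps 1 to 2, 2 to 3, 4 to 5 and 5 to 6. No offset gave 12 at step 3 to 4, the offset at the median 42 at step 4 to 5, and the filter at the 60th percentile 7 at step 2 to 3 and 13 at step 4 to 5. The cause was not tested for these. Only the 4 arrays compared gave 56, 46, 99, 92 and 240 at the steps, against 166, 14, 24, 23 and 131 in the reported fit. These fits have fewer arrays and take the spread from the 2 compared positions alone. Replicate pairs differed most at position 2 (0.52) and least at position 6 (0.32), so pooling the spread may contribute to the difference. Without the 3 brightest arrays there were 774 calls in the F test and 0, 1, 6 and 67 from step 2 to 3 on, with 967 at an unadjusted p under 0.05 where limma called 0. With the epidermal covariate there were 777 in the F test, 0 at step 1 to 2 (limma, 936 at an unadjusted p under 0.05) and 9 at step 4 to 5. With an estimated correlation camera called 1 list.

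With 1 array left out, counts ran from 319 to 664 (higher) and 288 to 565 (lower) at the ends, and from 84 to 251, 2 to 91, 9 to 35, 5 to 50 and 33 to 195 at the steps. Peaks ran from 106 to 226 at position 2, 43 to 88 at position 3, 67 to 177 at position 4 and 278 to 505 at position 6. The F test ran from 819 to 1434 and the trend from 541 to 891 (higher) and 459 to 740 (lower), all within 1.5 times the reported counts.

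Over all probe sets the replicate differences were nearly uncorrelated between positions: the 15 correlations ran from -0.0707 to 0.0848. This cannot exclude an effect of the replicate number on some genes. The centred means of the neural crest list and of the Notch and clock list were higher in replicate 2 at each of the 6 positions. Those of other lists, such as epidermis, went both ways. With the replicate number as a block there were 1320 calls in the F test, 805 higher and 701 lower along the trend, 616 higher and 531 lower at the ends, and 211, 15, 27, 29 and 170 at the steps.

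*eve1*, at 1.70 in the somites, had a trend of -5.14 to -10.19 depending on the setting, called in each. With no offset it lost its call at step 3 to 4, as *aldh1a2* and *nanos3* did; the cause was not tested, and with no detection calls in the table signal over background was not measured.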

Other observations

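The tests of the position 5 to 6 change (surface cells and maturing mesoderm) and the epidermal covariate were chosen after the result was seen, and the germ cell list was written after *nanos3* and *dnd1* had been seen, before its own test. Several genes had courses that a linear trend hides. *sp5l*, a Wnt target, dropped from 1255 ± 85.2 in the posterior PSM to 241 ± 10.9 in the center, returned to 1117 ± 38.3 in the anterior PSM (2.16, adjusted p = 0.000191) and ended at 485 ± 184 in the somites. *ier2a*, an immediate early gene, fell over the same stretch from 2248 ± 69.2 to 220 ± 17.3 and rose to 472 ± 129 in the somites (1.04, adjusted p = 0.0187). The glycosyltransferase gene *lfng*, which modifies Notch, fell from 1009 ± 450 to 251 ± 198 at the flank of the tailbud (adjusted p = 0.0266) and measured 1410 ± 288 in the somites.

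From the center to the flank of the tailbud *apoc1* rose from 2220 ± 8.34 to 4715 ± 692 and *apoeb* from 1186 ± 331 to 2370 ± 569, while *apoc2* was not called (2.11, adjusted p = 0.186). The blood list had a median change of 1.47 from position 3 to 4 with 0 of 20 genes called by limma (7 adjusted over the list alone, camera adjusted p = 2.31e-07, adjusted p = 0.378 with an estimated correlation, and by fry adjusted p = 0.277). The embryonic globin *hbae3* measured 1780 ± 1509 at position 4. Oxidative phosphorylation and ribosomal protein genes had medians of 0.23 and 0.24 from position 5 to 6, with 2 called higher in each list (camera adjusted p = 5.69e-05 and 9.04e-09, both adjusted p = 0.771 with an estimated correlation).

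A random assignment of the arrays to the positions is argued against for the trend and for the F test. Among 100 random assignments of the arrays to the positions, the real one included, only the real one gave as many calls. That was 1 of 100 for the trend, with 1434 real calls and 68 in the highest other, and 1 of 100 for the F test, with 1210 and 382. These assignments also split the replicate pairs. They therefore cannot say whether the order of the positions matters or what makes the pieces differ.

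Of 23 epidermal genes 9 were higher at position 2 than at position 1, with a list median of 1.96 (camera adjusted p = 0.326 with an estimated correlation). Brightness of the arrays is argued against: the median stayed at 1.80 under quantile normalization and 1.48 under median centring. Surface cells in the dissected pieces may contribute, since *krt4* and *cldni* reached 867 and 2217 at position 2, but *cldni* was at 371 in the center of the tailbud, no sort is described, 3 genes of the list are in other lists, and lists of other tissues moved the same way (medians of 1.53 for blood and endothelium and 1.19 for sclerotome). The other 111 probe sets higher at position 2 changed by a median of -0.56 from position 5 to 6, which surface cells would give. In the highest of the 4 pairs of arrays they changed by only -0.050, so that mesoderm maturing along the axis stays open too. The epidermal list itself changed by -0.36 in that pair and by -1.65 with the other somite array, so this test cannot separate the explanations. With the epidermal covariate step 1 to 2 had 0 calls by limma (936 at an unadjusted p under 0.05), but the covariate follows the positions and cannot separate these.

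*nanos3* and *dnd1*, which act in primordial germ cells, were highest at position 4. A fault of 1 array is argued against for these genes, because 2 of 2 arrays of position 4 exceeded all 10 other arrays for both, *nanos3* at 1317 and 304 against at most 70.9. The rule that named them already asked both arrays of position 4 to exceed both of position 5, so part of this was fixed in advance. Germ cells in these pieces may be the source. The 10 other germ cell genes measured had a median excess there of 1.08 in replicate 1 and 0.70 in replicate 2, against 0.03 and 0.08 for all genes. *tdrd7a* was at 192 and 105 against at most 20.7, but *ddx4* was at 140 and 5.30, so germ cells stay open.

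Ribosome biogenesis genes were higher toward the somites in 46 of 78 cases. Scaling of the arrays is argued against, since the list exceeded the median of all genes by 0.66 under quantile normalization and by 0.87 as deposited (median centring cannot change this difference). Abundance of the transcripts is argued against too: the list's median of 0.74 lay at percentile 100 of 10000 random lists matched on mean expression, whose highest was 0.35. A difference between the positions themselves, which the design names, may be the source, as a hypothesis. With an estimated correlation the list was not called (adjusted p = 0.118).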
